A study of Rattus norvegicus with 12 samples.

How the data were processed

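Messenger RNA was sequenced from the motor cortex of 12 rats (Rattus norvegicus), 3 in each of 4 groups. The groups are control rats, rats of the 6-OHDA model of Parkinson's disease (PD), stimulated control rats and stimulated PD rats, each assigned by its title. Each title numbers its rat within its group, so the libraries are separate animals. The hemisphere, the sex of the rats, a sham operation or sham array in unstimulated rats, and any cohort or library batch are not given in the sources used here. The design text names 3 groups, whereas the labels give 4, and whether the stated stimulation schedule also applied to stimulated controls is not said.

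Libraries were made with a stranded poly(A) RNA kit, per the labels' protocols. Trim Galore, STAR and featureCounts, without versions, and the rat assembly mRatBN7.2 are named in the submitters' processing notes. The annotation release, the strand setting and the normalization tool are not given in the sources used here. The deposited table holds CPM (each library's counted reads scaled to a common total), as calculated by the authors, for 16534 features under Ensembl rat gene identifiers. All 12 columns were matched to a sample by its short description, and 0 columns were left unmatched. No value in the table is 0, so a feature without a read in any library is not in it, and a gene silent in 1 group would not be seen here.

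Within each column every value was a whole multiple of a single step. Dividing by that step gave whole reads for 100% of values in each library, within a tolerance of 0.001 read, and a library total of 42905441 to 62082830 counted reads. Between 0.0190% and 0.130% of a library's reads lay outside the table. Averaged over features, counting error was small against the spread between rats: for within-group pairs of libraries the chi-square per feature ran from 31.2 to 266. This mean is weighted toward abundant features, and for low features counting error was not measured against the spread. Pearson's r between rats of a group was 0.961 to 0.992 on the log2 scale.

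The table has identifiers only, and no table used here pairs them with gene symbols: 0 of 16534 identifiers were matched. The 37 gene lists fixed before the data were examined (neuronal, glial, vascular, immune, activity-regulated, dopamine, mitochondrial and stress genes) are therefore not analysed here, and neither are gene positions, length or GC content. The rule fixed for naming genes took those with the largest fold change among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap between the libraries of the compared groups. Because symbols were lacking, at most 2 identifiers per direction are printed, for the comparisons of PD and of stimulated PD rats with controls; the other comparisons fixed beforehand had no feature passing the test, and their closest features are not given.

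The main test was limma (version 3.58.1, R 4.3.3) on log2(CPM + 0.5), with 1 coefficient per group, all 12 libraries in the fit and a trended prior variance, for the 14985 features with a mean of at least 0.5 CPM. A log2 fold change is on the log2(CPM + 0.5) scale, which understates the change of low features. P-values were two-sided and adjusted by Benjamini-Hochberg, and features with an adjusted p under 0.05 are called changed. The fit had 8 residual degrees of freedom. The 5 comparisons fixed before the data were examined were PD with control, stimulated PD with PD, stimulated control with control, stimulated PD with control, and the interaction. The comparison of stimulated PD with stimulated control, and the main effects of the lesion and of stimulation, were added after seeing the data. Here lesion stands for the 6-OHDA model as labelled: the PD and stimulated PD rats are called lesioned, and the others unlesioned.

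Fold changes of 2 comparisons were related by Pearson's r and covariance across features, which are not independent replicates. Because some comparisons share libraries, the values with no group effect were simulated by 100 random rotations of the residuals of the fit, which keep the shared libraries and the correlation between features; their range is that of the central 95% of simulations. The share of PD calls with the same sign in the stimulated pair was simulated in this way too, after seeing the data. All these simulations give the 4 groups the same spread. Each library was also placed on a scale from the control mean (0) to the PD mean (1) along the PD-minus-control direction. The direction was fitted without the PD or control library being measured and without the control library it was measured from, so that their noise does not enter both sides; this measure was added after seeing the data. Single values were compared by exact permutation tests. For the positions on this scale the direction was not refitted in each permutation, so those tests are not exact.

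Alternatives were other pseudocounts (0.1 and 2 CPM), no filter or a mean of 2 CPM, 4 rescalings (equal sums, median-of-ratios, TMM and quantile), no variance trend, library weights, a replicate block by the rat numbers of the titles and, added after seeing the data, by those of the sample descriptions, fits of the compared groups alone, each library left out, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered whole reads. The test was checked on simulated counts for the comparison of PD with control, drawn for the 14985 features with 100 features changed 2-fold and 100 changed 4-fold. It recovered 59% of the former and 89% of the latter in the right direction, with 10 false calls among 158, and it made 0 calls where no change was simulated. The simulated features varied independently, which real ones do not.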

Results

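Gene expression was measured in the motor cortex of rats in which 6-OHDA (6-hydroxydopamine, a toxin taken up by catecholamine neurons) had been used to model Parkinson's disease (PD), with and without electrical stimulation of the cortex. Stimulation was delivered through a graphene electrode array on the primary motor cortex at 130 Hz for 1 hour a day over 2 weeks; whether stimulated controls had this schedule is not stated. Control, PD, stimulated control and stimulated PD rats were profiled, with 3 rats in each group. Libraries held 50459597 ± 6699936 counted reads in control, 54432905 ± 7466087 in PD, 57000092 ± 984179 in stimulated control and 48392375 ± 3855999 in stimulated PD rats (mean ± SD, n = 3). Of 16534 features, 14985 had a mean of at least 0.5 CPM (counts scaled to a common library total) and were tested. Features are given by Ensembl gene identifier, since the files do not pair identifiers with gene symbols.

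The first principal component carried 48.0% of the variance. It placed the 3 PD libraries at its positive end, with scores of 33.2 to 58.2, whereas control libraries scored from -27.0 to -2.47 and stimulated control libraries from -49.7 to -11.3. Stimulated PD libraries spread from -18.8 to 27.8, below every PD library, and stimulated PD rat 2, at -18.8, lay within the range of the controls. On the second component (19.0%) the 3 stimulated PD libraries scored from -24.5 to -19.5, and PD rats 2 and 3 scored 41.2 and 9.66. PD rat 1 scored -28.5 and so lay beside the stimulated PD rats.

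**Figure D1:**
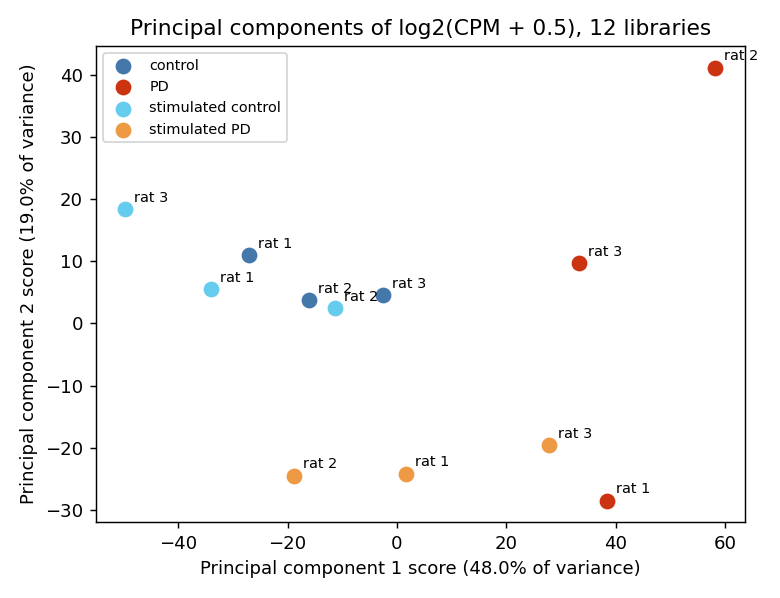
Scores of the 12 libraries on the first (x axis, 48.0% of variance) and second (y axis, 19.0%) principal component of log2(CPM + 0.5). Each point is 1 rat, coloured by group; PD rat 1, at -28.5, lies with the stimulated PD rats on the second component.

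The comparison of PD with control rats asked what the 6-OHDA model does to motor cortex expression. In PD rats 615 features fell and 42 rose by limma. The features that fell had a median log2 fold change of -1.16, a 2.23-fold lower level, and 374 of them fell more than 2-fold. The features that rose did so by a median of 0.68 on the log2 scale, and 6 rose more than 2-fold. Lower features were found at every abundance: 155 of the 3255 features with a mean below 5 CPM fell, as did 356 of the 7271 between 5 and 50 CPM and 104 of the 4459 at 50 CPM and above. The shift was smaller in abundant features. In these 3 classes the median log2 fold change of all features was -0.28, -0.11 and -0.04, and 5.0%, 5.1% and 2.7% were called in either direction. PD and control libraries did not overlap for 29.1% of the features tested, where chance gives 10% on average. Features are not independent, and how widely this share varies by chance was not measured, here or for the other comparisons.

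Among the features named by rule, ENSRNOG00000012067 rose from 0.473 ± 0.135 CPM in control to 16.7 ± 8.62 CPM in PD rats (SD, n = 3; log2 fold change 3.98, SE 0.45, limma adjusted p = 0.00795). ENSRNOG00000017286 rose from 3.60 ± 3.56 to 14.9 ± 6.46 CPM (n = 3; log2 fold change 2.16, SE 0.47, limma adjusted p = 0.0323), with control rat 1 at 7.71 CPM. ENSRNOG00000016164 fell from 72.5 ± 35.9 CPM in control to 1.47 ± 1.27 CPM in PD rats (n = 3; log2 fold change -5.24, SE 1.13, limma adjusted p = 0.0323). ENSRNOG00000043451 fell from 16.4 ± 6.30 to 0.196 ± 0.0835 CPM (n = 3; log2 fold change -4.52, SE 1.08, limma adjusted p = 0.0429). ENSRNOG00000012067 passed under 26 of 27 alternatives. The call was lost for ENSRNOG00000017286 without control rat 2 or 3, PD rat 2 or stimulated PD rat 1 and with only PD and control rats fitted (limma adjusted p = 0.0665), and for ENSRNOG00000016164 without any 1 control rat or PD rat 1 or 2. ENSRNOG00000043451 lost it in 13 of 26 alternatives, among them a pseudocount of 2 CPM, quantile normalization, no variance trend, and leaving out any 1 control or PD rat or stimulated control rat 1 or 2.

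The number of features called between PD and control rats depended on single libraries and on scaling. Without control rat 1, 2 or 3 it was 4, 52 or 251, without PD rat 2 it was 86, and without stimulated PD rat 1 or stimulated control rat 1, which enter only the estimate of spread, it was 291 and 295. Lower features made up 93.6% of the calls as deposited, 76.9% with median-of-ratios factors, 68.7% with TMM factors, 68.1% after quantile normalization, 77.7% by edgeR and 56.0% by DESeq2. The median log2 fold change of all features was -0.11 as deposited, and 0.04, 0.04 and 0.05 under those 3 rescalings.

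**Figure D2:**
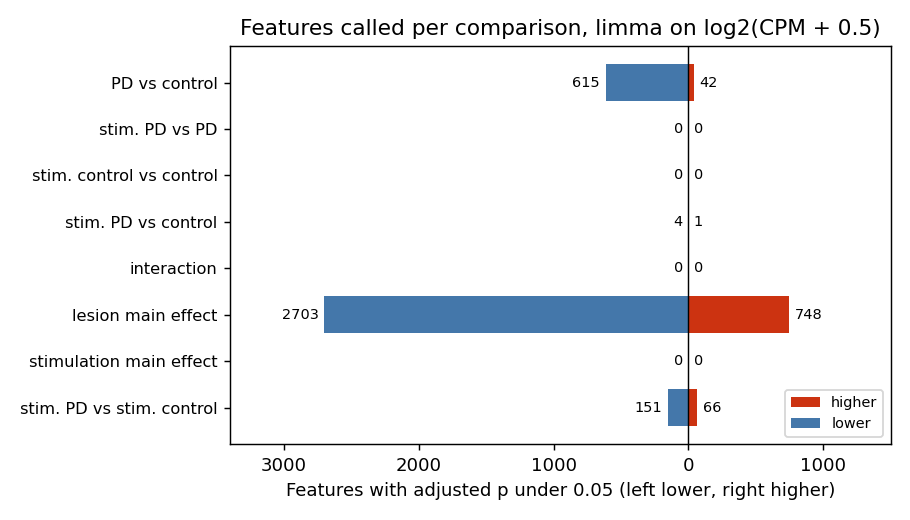
Number of features with a limma adjusted p under 0.05 in each comparison (x axis, lower features to the left and higher to the right; y axis, the comparison). PD rats had 615 lower and 42 higher features against controls, while 0 features passed for stimulation in PD or in control rats.

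The difference between lesioned and unlesioned rats was measured again among stimulated rats, which share no library with the unstimulated ones. In stimulated PD rats 151 features were lower and 66 higher than in stimulated controls. Of the 615 features that fell in PD rats, 590 (95.9%) had a negative estimate in this pair of groups, 347 of them with an unadjusted p under 0.05 and 51 with a limma adjusted p under 0.05. Of the 42 that rose, 41 (97.6%) had a positive estimate and 17 passed. Simulations with no effect in the stimulated pair gave ranges that ended at 92.4% for the former share and 81.0% for the latter. The p-values of both pairs rest on the same residual variance per feature, so the calls they share are not independent. A cohort or library batch that followed the lesion, which the labels do not give, would also be shared by both pairs. Over all features, 63.7% had a negative estimate in the stimulated pair. The median log2 change of the 615 features was -0.57 in stimulated and -1.16 in unstimulated rats, on whose libraries they had been selected. Across all tested features, which are not independent replicates, the fold changes of both pairs correlated with r = 0.55, where simulations with no effect ranged from -0.46 to 0.45, and the covariance was 0.101 (simulated -0.0311 to 0.0298). Without PD rat 1 or stimulated PD rat 3, r was 0.39 or 0.37, inside the range simulated for all 12 libraries.

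Counts in the stimulated pair moved with settings and libraries. Lower features were 69.6% of the 217 calls as deposited, 57.1% of 14 calls with median-of-ratios factors, 31.3% of 550 with TMM factors, 36.2% of 740 after quantile normalization, 46.7% of 15 by edgeR and 48.5% of 2019 by DESeq2. Without control rat 1, 2 or 3 the count was 6, 3 or 3, without PD rat 1, 2 or 3 it was 1877, 2256 or 579, without stimulated control rat 1, 2 or 3 it was 3, 875 or 2, and without stimulated PD rat 1, 2 or 3 it was 3, 2 or 2.

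With both pairs combined, 2703 features were lower and 748 higher in the 6 lesioned than in the 6 unlesioned rats, and 642 of the 657 PD calls were among them with the same direction. The median log2 fold change was -0.61 for the lower and 0.37 for the higher features. Lower features were 78.3% of these calls as deposited, 50.5% with median-of-ratios factors, 46.0% with TMM factors, 44.2% after quantile normalization, 50.1% by edgeR and 49.3% by DESeq2, so which direction was in the majority depended on scaling and tool. Without control rat 1 or 2, stimulated control rat 3 or stimulated PD rat 1 there were 1950, 2149, 1881 and 2250 calls.

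The reads of lesioned rats were also concentrated in fewer features. The 10 most abundant features took 10.5% ± 1.12 of reads in lesioned and 8.07% ± 0.475 in unlesioned rats (SD, n = 6), with the lowest lesioned library at 9.44% and the highest unlesioned at 8.71% (exact permutation test within stimulated and within unstimulated rats, two-sided, p = 0.005, the smallest it can give). By group the share was 8.37% ± 0.506 in control, 10.5% ± 0.774 in PD, 7.76% ± 0.157 in stimulated control and 10.5% ± 1.59 in stimulated PD rats (SD, n = 3). Of these 10 features, 7 were higher in lesioned rats by limma as deposited and with TMM or median-of-ratios factors, and 0 after quantile normalization, which gives every library the same highest values. Features below 1 CPM numbered 2825 to 2976 in PD and 2308 to 2496 in control libraries, but 2410 to 2768 in stimulated PD and 2126 to 2500 in stimulated control libraries, so on this measure lesioned and unlesioned rats overlapped.

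The comparison of stimulated PD with PD rats asked what stimulation changes in the model. By limma, 0 features passed at an adjusted p under 0.05, with a smallest adjusted p of 0.149, although 2613 features (17.4%) had an unadjusted p under 0.05, 1757 of them higher and 856 lower in stimulated PD rats. edgeR also called 0 features, and DESeq2 called 907, of which 548 were higher and 359 lower. Stimulated PD and PD libraries did not overlap for 14.2% of features, against 10% by chance. Without PD rat 1, 1528 features were higher and 1415 lower in stimulated PD rats, and without stimulated PD rat 3 there were 325 higher and 2 lower. ENSRNOG00000016164 stood at 81.7 ± 98.3 CPM in stimulated PD and 1.47 ± 1.27 CPM in PD rats (n = 3; log2 difference 4.16, SE 1.13, limma adjusted p = 0.203). ENSRNOG00000012067 stood at 28.7 ± 14.7 and 16.7 ± 8.62 CPM (n = 3; log2 difference 0.80, SE 0.45, limma adjusted p = 0.338).

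**Figure D3:**
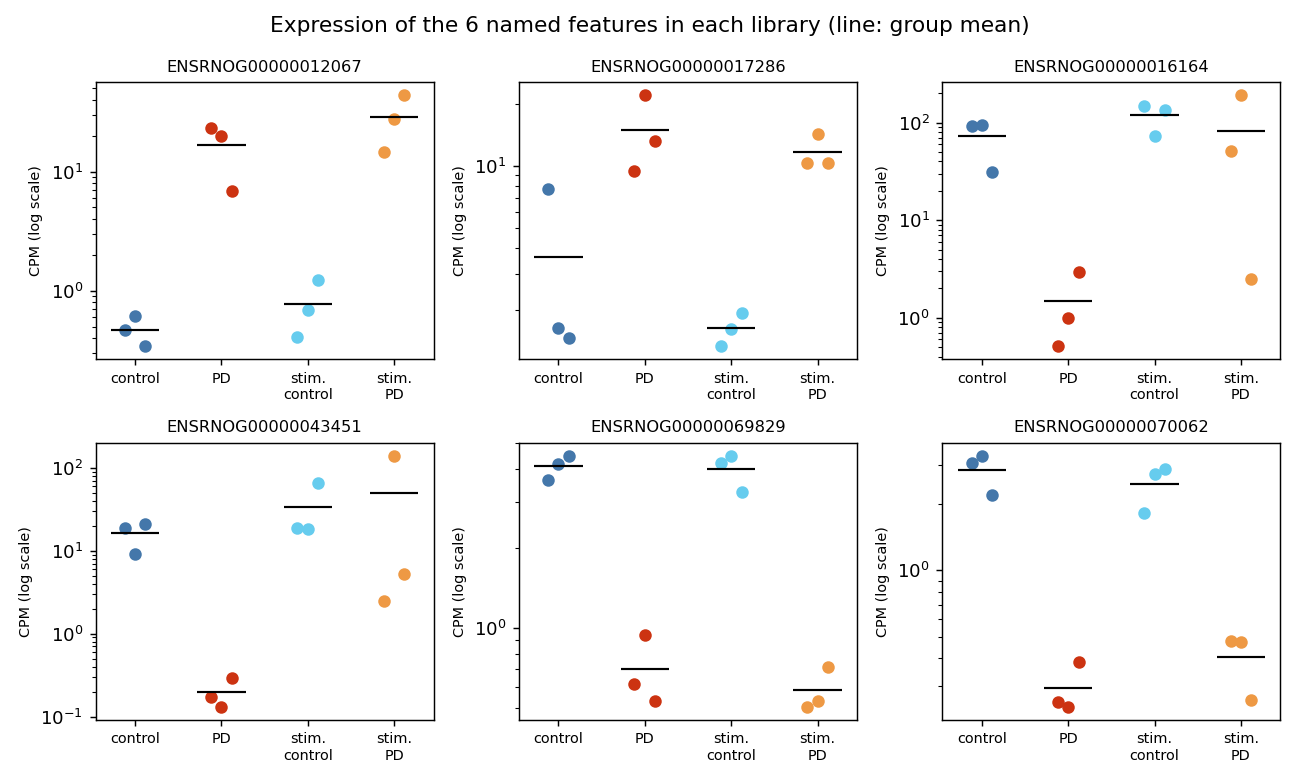
Expression (y axes, CPM on a log scale) of the 6 named features in each library, by group (x axes); points are rats and lines are group means (n = 3). ENSRNOG00000012067 is at 6.93 CPM or more in the 6 lesioned rats and at most 1.24 CPM in the 6 unlesioned rats, while ENSRNOG00000016164 ranges from 2.52 to 192 CPM among stimulated PD rats.

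Whether stimulation moved expression against the PD change was examined across features. Fold changes of stimulated PD against PD rats correlated with those of PD against control rats at r = -0.72. The PD libraries enter both with opposite sign, and simulations with no effect gave a mean r of -0.47 and a range of -0.76 to -0.05, with 11 of 100 as low. The covariance was -0.142 against a simulated mean of -0.0281 (-0.0600 to -0.00230), a difference of -0.114, and 0 of 100 simulations were as low. However, the simulations gave all groups the same spread. Pearson's r between rats was 0.961 to 0.984 in PD and 0.989 to 0.992 in control. The simulated covariance may therefore be too small in size for the more variable PD rats, so this difference does not establish a movement against the PD change. Of the 615 features that fell in PD rats, 586 (95.3%) had a positive estimate in stimulated PD against PD rats, 365 of them with an unadjusted p under 0.05 by limma, and the median was 0.62. Of the 42 that rose, 30 (71.4%) had a negative estimate, 7 with an unadjusted p under 0.05 by limma, and the median was -0.17 against 0.68 in PD rats. Both shares lie within the range simulated for lower and higher features together, selected in this way (69.0% to 99.9%). These simulations held no PD effect, so the features selected in them were noise alone. Features with a real PD change would reverse less often by selection, so this range cannot tell whether the shares are unusual. The simulated range of r has the same limit. Adjusted over each list alone, 298 and 4 passed by limma, which is not independent evidence because the lists were chosen on the same PD libraries.

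On a scale from the control mean (0) to the PD mean (1), stimulated PD rats stood at 0.395 ± 0.437 (SD, n = 3), with single values of 0.353, -0.0195 and 0.852. PD rats stood between 0.904 and 1.05 and control rats between -0.318 and 0.325. Each stimulated PD library lay below each PD library (difference -0.605, permutation test, two-sided, n = 3 against 3, p = 0.1, the smallest this design allows). The permutations exchanged finished positions without refitting the direction, which rests on the PD and control labels, so this test is not exact. Stimulated control rats stood at -0.290 ± 0.301 (difference from control -0.290, n = 3 against 3, same permutation test, p = 0.5).

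**Figure D4:**
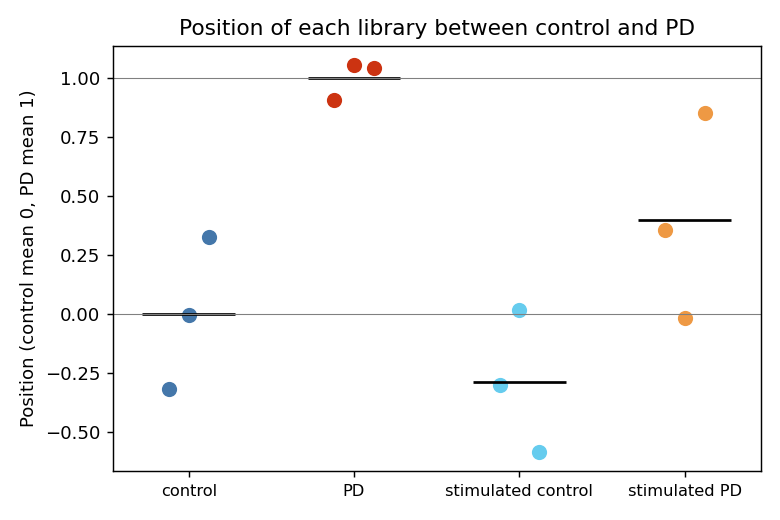
Position of each library (y axis, no unit) on a scale where the control mean is 0 and the PD mean is 1, by group (x axis); points are rats and lines are group means (n = 3). Stimulated PD rats lie between -0.0195 and 0.852, below the lowest PD rat at 0.904.

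In control rats, stimulation gave 0 features with a limma adjusted p under 0.05 and a smallest adjusted p of 1.00. Here 268 features (1.79%) had an unadjusted p under 0.05, and both edgeR and DESeq2 called 0. Libraries of stimulated and unstimulated controls did not overlap for 8.88% of features, against 10% by chance. A difference between the stimulation effects in PD and control rats (the interaction) was called for 0 features by limma and by edgeR and for 30 by DESeq2, with 619 features at an unadjusted p under 0.05. Averaged over PD and control rats, stimulation changed 0 features by limma and edgeR and 289 by DESeq2, with 2057 at an unadjusted p under 0.05, and 534 by limma without PD rat 1.

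The stimulation effects in PD and in control rats, which share no library, correlated across features with r = 0.32, within the simulated range of -0.46 to 0.47, and with r = 0.21 without control rat 3. Their covariance was 0.0301, also within the simulated range (-0.0268 to 0.0329). Stimulated controls against controls and PD rats against controls correlated with r = -0.27, whereas their shared control libraries alone gave a mean of 0.49 (0.04 to 0.80) in simulations. The covariance was -0.0271, against a simulated mean of 0.0300 (0.00211 to 0.0676), and r was -0.11 without control rat 2, -0.12 without control rat 3 and -0.07 without stimulated control rat 3. Because the simulations gave all groups the same spread, their values may be too high for the less variable controls.

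**Figure D5:**
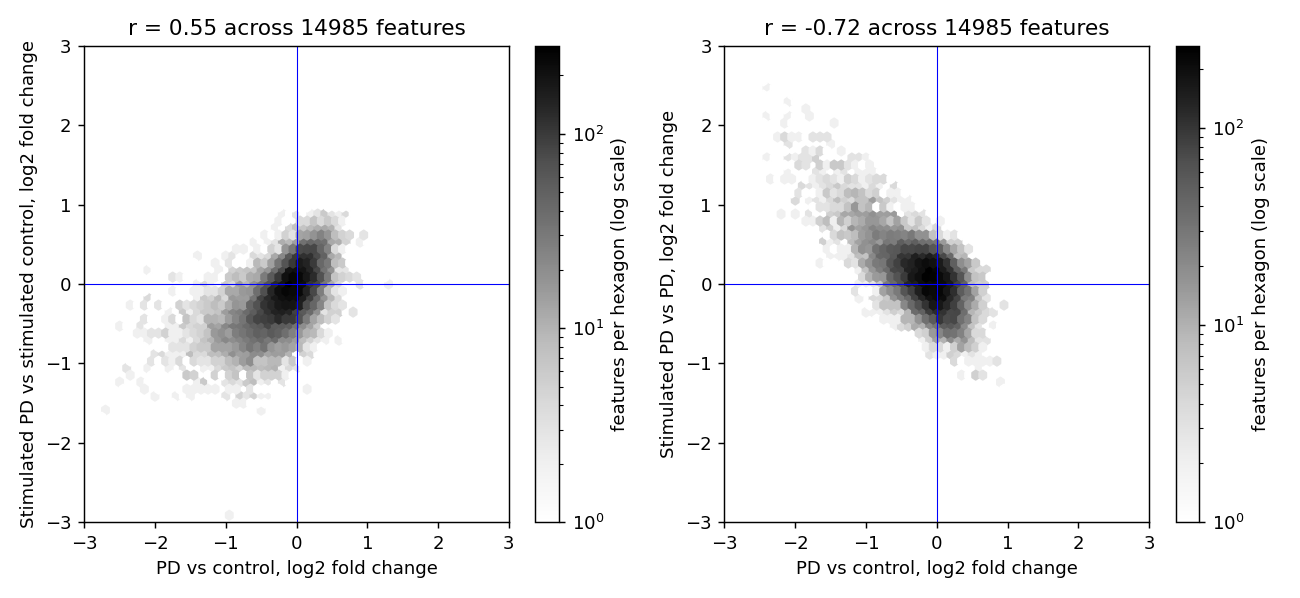
Log2 fold changes of 14985 features for PD against control (x axes) and, on the y axes, for stimulated PD against stimulated control (left, r = 0.55) and for stimulated PD against PD (right, r = -0.72). Shading gives features per hexagon on a log scale, and 26 and 28 features lie beyond the plotted range of 3; the pairs on the left share no library, those on the right share the PD libraries.

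Stimulated PD rats were compared with controls to see how far they lay from them. By limma, 4 features were lower and 1 was higher, against 3 lower and 2 higher with TMM, median-of-ratios or quantile rescaling. This count rests on a spread pooled over all 4 groups, PD rats included. It was 2859 with only the 2 compared groups fitted, so it is no measure of how near stimulated PD rats lay to controls. The 5 features were also called in PD against control with the same direction, where independent lists would share 0.164 lower and 0.00280 higher features. Both comparisons use the same 3 control libraries, too few to split, and the same residual variance per feature, so part of this overlap may come from these. ENSRNOG00000012067 was the higher feature, at 28.7 ± 14.7 CPM against 0.473 ± 0.135 CPM (n = 3; log2 fold change 4.79, SE 0.45, limma adjusted p = 0.00171). ENSRNOG00000069829 was lower, at 0.580 ± 0.113 against 4.10 ± 0.431 CPM (n = 3; log2 fold change -2.09, SE 0.19, limma adjusted p = 0.00171). ENSRNOG00000070062 was lower too, at 0.404 ± 0.126 against 2.86 ± 0.585 CPM (n = 3; log2 fold change -1.89, SE 0.21, limma adjusted p = 0.00749), a call lost without control rat 1 or 2.

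In this comparison 3135 features had an unadjusted p under 0.05, and 41.4% of features did not overlap between the groups, where chance gives 10%. With only stimulated PD and control rats fitted, 1783 features were lower and 1076 higher by limma, whereas DESeq2 with all 4 groups fitted called 413 lower and 670 higher. These fits differ in scaling and in the groups fitted as well as in the tool. Which of these turned the majority was not tested. Without PD rat 1, 2 or 3, which enter only the estimate of spread, the number was 1108, 1227 or 71; without control rat 1, 2 or 3 it was 3, 2 or 3, and without stimulated PD rat 2 it was 3.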

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

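Comparisons of stimulated PD with stimulated control rats, both main effects, the correlation between the lesion differences, the block of description numbers, and correlations with TMM, median-of-ratios, edgeR and DESeq2 were added after the data were seen. The 4 correlations kept their sign in 20 alternatives, in the ranges -0.79 to -0.65 (PD with stimulation in PD rats), -0.33 to -0.07 (PD with stimulation in controls), 0.21 to 0.40 (both stimulation effects) and 0.37 to 0.65 (both lesion differences). Stimulation in control rats gave 0 calls under its 27 alternatives. DESeq2 called 2037 features for PD against control, 907 for stimulated PD against PD, 1083 for stimulated PD against control, 30 for the interaction, 4366 for the lesion, 289 for stimulation and 2019 for stimulated PD against stimulated control; it gave no adjusted p for 1759 features in stimulated PD against control and for 22 in each other comparison. Library weights gave 5579, 8725, 5036, 3928, 7771, 6556 and 6381 in that order, but their estimation did not converge and put a weight of 52.0 on PD rat 3. Fitting only the compared groups gave 2859 for stimulated PD against control and 2163 for stimulated PD against stimulated control. Quantile normalization gave 295 for PD against control. The majority turned from lower to higher features for the lesion with TMM (3498 calls), quantile (3225) and DESeq2 (4366), and for stimulated PD against stimulated control with TMM (550), quantile (740), edgeR (15), DESeq2 (2019) and without stimulated PD rat 1 (3). It also turned for stimulated PD against control, with DESeq2 (1083), the block of description numbers (1) and without control rat 1 (3). Stimulated PD against stimulated control also gave 14 with median-of-ratios factors, 41 without a filter and 33 without a variance trend. Leaving out each library gave 4 to 976 for PD against control, 0 to 2943 for stimulated PD against PD, 2 to 1227 for stimulated PD against control, 1881 to 4608 for the lesion, 0 to 534 for stimulation and 2 to 2256 for stimulated PD against stimulated control. For these changes the cause was not tested. Rats are numbered by the titles and, otherwise for PD and stimulated PD rats, by the sample descriptions. Deviations of same-numbered rats correlated between -0.46 and 0.36 by title (3 of 18 pairs above 0.1) and between -0.46 and 0.16 by description (1 of 13). Under either numbering, 2 of 12 libraries correlated best with their own number. A pairing by number was therefore not seen. With so few rats, a litter or library batch shared by some same-numbered rats cannot be excluded. The replicate block by title gave 282 calls for PD against control, 2 for stimulated PD against control and 2 for stimulated PD against stimulated control; that by description, with 5 residual degrees of freedom, gave 0, 1 and 23, and 1461 for the lesion. No other count moved by over 1.5 times. ENSRNOG00000017286, ENSRNOG00000043451 and ENSRNOG00000070062 lost their calls under both blocks, and ENSRNOG00000012067 and ENSRNOG00000016164 (PD against control) and ENSRNOG00000069829 under the second. The planned gene list tests were not run because identifiers were not matched to symbols. Averaged over features, rats of a group differed by at least 31.2 times the counting error (chi-square per feature). This mean is weighted toward abundant features, so it does not show that counting depth adds little to the spread of low features. Features without a read in some library are outside the table.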

Other observations

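Tests of scaling, of a difference limited to unstimulated libraries, of exchanged libraries, of depth, of a cohort and of the position between control and PD rats were chosen only after the results they bear on had been seen, and so were the comparisons of lesioned with unlesioned rats, of stimulation averaged over both, and of stimulated PD with stimulated control rats.

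A small set of features separated all 6 lesioned from all 6 unlesioned rats: 18 had a gap of at least 0.5 on the log2 scale between the nearest rats, 14 lower and 4 higher in lesioned rats, whereas 99 other splits gave at most 1. ENSRNOG00000069829 stood at 0.502 to 0.944 CPM in lesioned and 3.27 to 4.49 CPM in unlesioned rats. A cohort, litter or library batch that followed the lesion, none of which the labels give, cannot be told apart from an effect of 6-OHDA for these 18 features. The same limit holds for every comparison of lesioned with unlesioned rats given here, the share of reads in the most abundant features included. A change that scales with the strength of the PD change in each rat stays open too: the share kept in stimulated rats was larger by 0.32 for the 50 calls with the smallest p than for the 50 with the largest fold change. A margin this large had been set beforehand as evidence against it, but that bound was wrong, since features picked by fold change had a median standard error of 0.59 against 0.24 and selection alone lowers the share they keep.

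The excess of lower features in PD against control rats may come in part from scaling. Quantile normalization brought lower features from 93.6% to 68.1% of the calls, between the bounds set for and against scaling as the whole cause, so scaling stays open. A difference found only in the 6 unstimulated libraries is argued against for CPM as deposited. Of the features that fell, 95.9% also had a lower estimate in stimulated PD than in stimulated control rats. The range simulated with no effect there ended at 92.4%. Under other scalings this share was not computed, and a scaling shift common to both pairs would raise it too. An effect of the lesion on RNA content stays open as untested.

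The comparison of stimulated PD with PD rats changed from 0 to 2943 calls when PD rat 1 was left out. This library correlated better with stimulated PD rats (mean r = 0.981) than with PD rats 2 and 3 (mean r = 0.972). The latter mean joins r = 0.961 with PD rat 2 and r = 0.984 with PD rat 3, so PD rat 2 lowers it. PD rat 2 correlated less with the other PD rats (mean r = 0.970) than PD rat 1 did. On the first principal component PD rat 1 scored 38.4, among the PD libraries. With all libraries thinned to 42884227 reads, the margin in favour of stimulated PD rats was 0.00840 in r, against 0.00831 before. No correlation between libraries moved by more than 0.000356, so counting error at these totals is too small to give this margin. Thinning could not have removed the margin and bears on counting error alone. Other differences that go with depth stay open as untested. An exchange with stimulated PD rat 3 stays open: that split gave 5 calls against 0 for the deposited labels, but stimulated PD rat 3 correlated better with its own group than with PD rats 2 and 3, by 0.00619 in r, the smallest such margin. A single wrong label, and a PD rat with a weaker or different lesion, stay open as untested.

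A hypothesis from these data is that stimulation may move expression in PD rats part of the way toward control. The mean position of stimulated PD rats was 0.395 on the scale from control (0) to PD (1), and single rats ranged from -0.0195 to 0.852, below the lowest PD rat (0.904). This restates the order of the same rats on the first principal component, from which the hypothesis was drawn, and is no independent support for it. Stimulated control rats stood at -0.290 ± 0.301 (SD, n = 3), so a movement particular to PD rats is not shown. With 3 rats against 3 the permutation p cannot go below 0.1, so the hypothesis stays open.

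For the lesion, 3451 features differed, against at most 1 in 99 other splits that exchanged the label within stimulated and within unstimulated rats. Of 100 splits, 1, the real one, gave as many, so a random exchange of labels is an unlikely source of that count. A cohort, litter or library batch that followed the lesion could give such a count too, and the splits cannot tell it from the lesion. The comparison itself was chosen after the data had been seen. Splits of 3 against 3 number 10, too few for a share under 0.05. The real value was 657 for PD against control (highest other 0; 1 split as large), 5 for stimulated PD against control (highest other 0; 1 split), and 217 for stimulated PD against stimulated control (highest other 1; 1 split). Where the real count is 0, every split gives as many, so splits decide nothing about chance. This holds for stimulated PD against PD (10 of 10 splits; highest other 5), stimulated control against control (10 of 10; highest other 11), the interaction (100 of 100; highest other 0) and stimulation averaged over both (100 of 100; highest other 42).

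Reads outside the table were most frequent in stimulated control rat 1, at 0.130% of its total, against 0.0190% to 0.0659% in the other libraries.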
